A study of Mus musculus with 12 samples.

How the data were processed

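The series holds 12 samples of CD45-positive cells from mouse tumours, 3 gene expression and 3 TCR samples for each of LNP-Ctrl and LNP-P20-mAb. Only the 6 TCR samples had processed files to work from, and the gene expression samples were not analysed here. Samples were assigned to treatments by their titles, which also give the replicate numbers 1 to 3. Per the labels' protocols, tumours of about 50 to 100 mm³ received 1 intratumoral dose, were dissociated enzymatically, and viable CD45-positive leukocytes were sorted. About 10000 sorted cells per sample went into 10x Genomics 5′ version 2 libraries with V(D)J enrichment of TCR transcripts. The time of harvest is not given in the sources used here.

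The deposited files list assembled TCR chains, 1 per line, with the cell barcode, the V, D, J and C segments, the CDR3 in amino acids and bases, and counts of reads and UMIs per chain. The submitters' processing notes name Cell Ranger 8.0.1. They also name mouse genome builds without a role, so no coordinates are given. Every deposited chain was marked as productive, full length, of high confidence and from a called cell. Read and UMI counts are raw counts per chain as the authors deposited them. The calling of cells and of chains was the authors', and it can affect the measurements, since a chain with few UMIs or a cell dropped before deposit leaves no trace in these files.

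Productive TRA and TRB chains were used, with a chain listed more than once on a barcode counted once. Barcodes with 2 or more TRB or 3 or more TRA chains were left out as candidate doublets (1844 barcodes with 2 TRB chains in all), and cells had to have at least 1 chain of each kind. A clonotype was the set of cells in a library with the same TRB chain (V, J and CDR3 bases) and a shared TRA chain. Because libraries differ in cell number, expansion measures were computed on 2016 cells per library, the size of the smallest, as the mean of 200 random draws. Overlap between libraries used 392 distinct TRB receptors per library (200 draws) and similarity of CDR3 loops the same number (50 draws). Expanded share means cells in clonotypes of 2 or more cells, and comparisons of clonotypes within libraries set clonotypes of 3 or more cells against single-cell clonotypes. Clonality is 1 minus the Shannon entropy divided by its maximum. Shares of single libraries have 95% exact Clopper-Pearson binomial intervals, and a count of 0 is given with the share that 3 counts would make. Both cover counting error only. Libraries held 2016 to 3923 usable cells, so that a share of 0 in the smallest allows up to 0.149%.

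Each library was 1 replicate. Single values were compared between treatments with exact permutation tests over the 20 assignments of 6 libraries, two-sided, whose smallest p is 0.1, and with 10 assignments and the same smallest p where LNP-P20-mAb 1 and 2 counted as 1 sample. Differences within libraries were tested with exact sign-flip permutation tests over 64 flips, whose smallest p is 0.03125. Overlap and public receptors were compared, one-sided, over the 10 distinct splits of the libraries into 3 and 3.

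Segment usage was tested with edgeR 4.0.16 (quasi-likelihood fit and F test) in R 4.3.3 on the number of distinct clonotypes per V and J segment, with the number of clonotypes as library size and no further scaling. Segments with 30 or more clonotypes over all libraries were tested (152), p-values were adjusted by Benjamini-Hochberg over all of them, and the threshold was an adjusted p of 0.05. The comparison by expansion used the library as a block, and its difference between treatments was an interaction term. The standard error of a log2 change was approximated as its size divided by the square root of the F statistic. DESeq2 1.42.0 was an alternative, and adjusted p-values that it left undefined stayed undefined. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. TRAV segments with D and N in their names are near-identical copies, and reads of such copies could be split between names, so counts of single copies are uncertain.

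The segment test was tested on simulated data, with 30 of 152 segments changed in 20 draws. For usage between treatments it recovered 67.5% of 2-fold and 91.1% of 4-fold changes and called 0.451% of unchanged segments. For usage by expansion it recovered 22.8% of 2-fold and 63.6% of 4-fold changes and called 0.328% of unchanged segments. In each comparison the simulated libraries were drawn independently, with the same dispersion for all segments. These rates therefore do not cover libraries that share clones, as some LNP-P20-mAb libraries did, or segments with a wider spread between libraries. In 20 simulated repertoires without noise or thinning the computed expanded share equalled the planted one, and 25 of 25 planted pairs of alike CDR3 loops were found. Both outcomes were fixed by construction, so these checks cover the arithmetic only and not the effect of sampling.

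The segments to be named were fixed before the data were examined, as were the tests, the lists and the alternatives unless stated otherwise. They are the segments past the threshold (at most 6 per direction and locus) and, because fewer than 10 passed, the 3 highest and 3 lowest TRBV, TRAV and TRAJ segments and the highest and lowest TRBJ segment, given as values. The lists are the Vβ8 family (TRBV13-1, TRBV13-2, TRBV13-3), the Vβ5 family (TRBV12-1, TRBV12-2), beta segments of iNKT cells (TRBV1, TRBV13-2, TRBV29) and of MAIT cells (TRBV13-2, TRBV13-3, TRBV19), and the V alpha segments near the J cluster (TRAV17, TRAV18, TRAV19, TRAV21). iNKT-type and MAIT-type cells were defined by alpha chain alone. Clonotypes named are the 2 largest of each library, receptors specific to a treatment with most cells (at most 5 each) and the receptors found in 4 or more libraries. Alternatives covered the clonotype definition, thinning, surplus chains, a minimum of 2 UMIs, weighting by cells, TMM scaling, DESeq2, no filter, copies summed, a replicate block and each library left out in turn.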

Results

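T cell receptor (TCR) libraries were sequenced from immune cells of subcutaneous mouse tumours. The tumours were grown in C57BL/6 mice from MC38, a mouse colon carcinoma line, in a derivative that the labels call a p53 knockout and to which they assign, in conflicting notations, a p53 substitution. On day 10 after engraftment the tumours were injected once with 40 µg of LNP-Ctrl or of LNP-P20-mAb, where the series concerns an antibody against frequent mutant forms of p53. Cells bearing CD45, the surface marker of leukocytes, were sorted by flow cytometry, and about 10000 of them per sample went into droplet-based 5′ single-cell libraries with enrichment of the TCR transcripts. There were 3 TCR libraries per treatment, and 6 matching gene expression samples were not analysed here. The stated purpose was to find how tumour-infiltrating T cells and NK cells differ between the treatments, and TCR libraries address the T cells.

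The 6 libraries held 5050 to 9982 assembled receptor chains on 2446 to 4869 cell barcodes, supported by 85835 to 145847 unique molecular identifiers (UMIs). LNP-Ctrl libraries held 4368 ± 512 T cell barcodes (SD, n = 3) and LNP-P20-mAb libraries 3372 ± 871, with an exact permutation p = 0.2. Both an alpha (TRA) and a beta (TRB) chain were recovered for 89.8% ± 2.80 of LNP-Ctrl barcodes and 91.1% ± 0.214 of LNP-P20-mAb barcodes (n = 3 each; exact permutation p = 0.7). The median number of TRB UMIs per paired cell was 16.7 ± 3.79 in LNP-Ctrl and 19.3 ± 1.53 in LNP-P20-mAb libraries (n = 3 each; exact permutation p = 0.4), and that of TRA UMIs was 7.0 ± 1.73 and 8.33 ± 0.577 (n = 3 each; exact permutation p = 0.4). No chain of a gamma-delta T cell receptor or of an immunoglobulin was present (0 of 48792 chains). After barcodes with surplus chains were removed, 2016 to 3923 paired cells per library remained, 19115 in all. The labels do not state that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. Tests of single values in 3 against 3 libraries were two-sided exact permutation tests over 20 assignments, which cannot go below p = 0.1.

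Most T cells from LNP-P20-mAb tumours belonged to expanded clones, while most T cells from LNP-Ctrl tumours carried a receptor found in a single cell. With every library thinned to 2016 paired cells, clonotypes of 2 or more cells held 75.5% ± 16.3 of LNP-P20-mAb T cells and 26.8% ± 19.96 of LNP-Ctrl T cells (SD, n = 3 each). Clones of 20 or more cells held 53.5% ± 18.9 of T cells in LNP-P20-mAb and 12.8% ± 13.4 in LNP-Ctrl libraries, and single-cell clonotypes held 24.5% ± 16.3 and 73.2% ± 19.96. The 10 largest clonotypes together held 46.7% ± 12.7 of LNP-P20-mAb T cells and 15.6% ± 13.4 of LNP-Ctrl T cells. Repertoires of LNP-P20-mAb tumours held 595 ± 355 distinct clonotypes among those 2016 cells and LNP-Ctrl repertoires 1557 ± 380.

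By library, the expanded share was 48.6%, 22.4% and 9.45% in LNP-Ctrl 1, 2 and 3 and 85.1%, 84.8% and 56.7% in LNP-P20-mAb 1, 2 and 3. No LNP-P20-mAb library overlapped the LNP-Ctrl range in expanded share, top 10 share, clonality or number of clonotypes, each at the smallest p of the exact permutation test (p = 0.1). With the deposited clonotype numbers the treatments overlapped in clonality (difference 0.171, exact permutation p = 0.2). Clonality, which is 0 for clonotypes of equal size and nears 1 for a single dominant clone, was 0.246 ± 0.0642 in LNP-P20-mAb and 0.0705 ± 0.0787 in LNP-Ctrl libraries (n = 3 each). Intermediate clones showed smaller gaps. Clonotypes of 5 to 9 cells held 6.86% ± 1.05 of LNP-P20-mAb and 3.73% ± 2.29 of LNP-Ctrl T cells (n = 3 each; exact permutation p = 0.3), those of 10 to 19 cells held 8.32% ± 1.99 and 3.06% ± 3.03 (n = 3 each; exact permutation p = 0.2), and those of 2 to 4 cells held 6.90% ± 3.58 and 7.24% ± 1.75 (n = 3 each; exact permutation p = 1). Adjusted by Benjamini-Hochberg over the 5 size classes, the lowest p of these exact permutation tests was 0.25, and over all 22 single-value comparisons of the treatments it was 0.244. Without thinning, the expanded share was 76.4% ± 15.6 in LNP-P20-mAb and 29.5% ± 19.6 in LNP-Ctrl libraries.

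The number of clonotypes of 3 or more cells was 83.3 ± 18.8 per LNP-P20-mAb library and 72.7 ± 26.6 per LNP-Ctrl library (n = 3 each; exact permutation p = 0.7). Single-cell clonotypes numbered 647 ± 467 and 2614 ± 860 (n = 3 each; exact permutation p = 0.1). LNP-P20-mAb 1 and 2 shared clones that held most of their cells. With the mean of both counted as 1 sample, an alternative chosen after the data were seen, the gap in expanded share was 44.0 percentage points instead of 48.7, and its exact permutation p became 0.2, as it did for clonality, the top 10 share and the number of clonotypes.

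**Figure D1:**
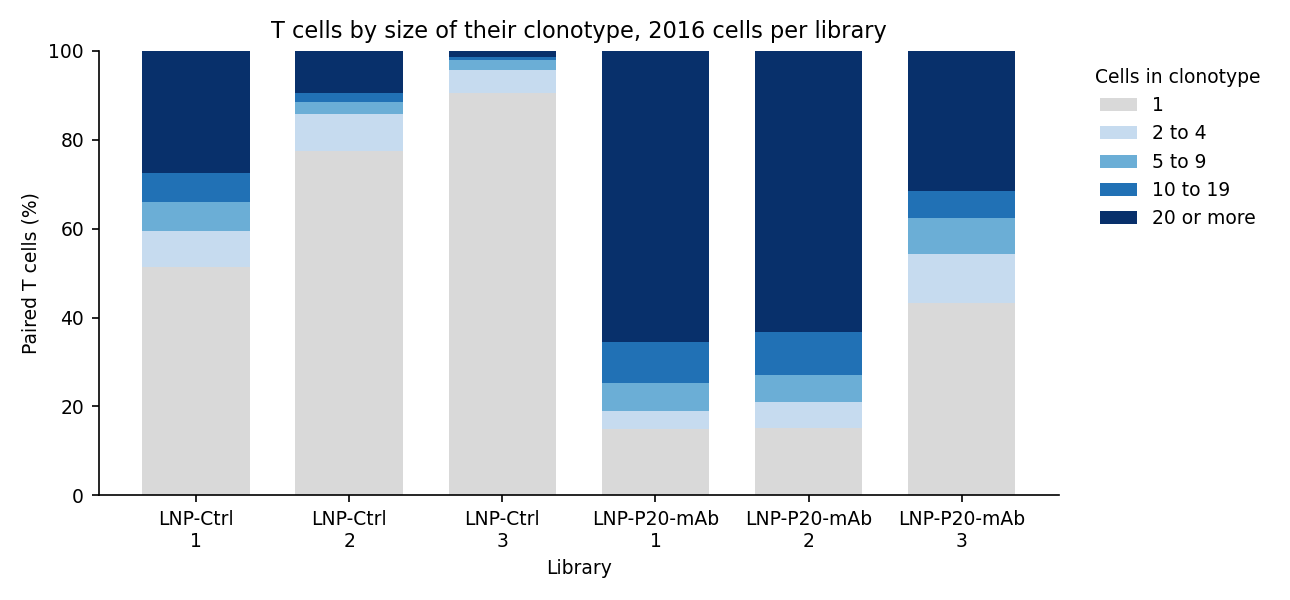
Share of paired T cells (%, vertical axis) in each of the 6 TCR libraries, split by the number of cells in the clonotype they belong to, as the mean of 200 draws of 2016 cells per library; each bar is 1 library and has no error bar. Clonotypes of 20 or more cells hold 65.4%, 63.3% and 31.7% of cells in the LNP-P20-mAb libraries and 27.6%, 9.50% and 1.34% in the LNP-Ctrl libraries.

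LNP-P20-mAb 1 and 2 carried largely the same T cell clones. They shared 116 clonotypes with identical TRA and TRB bases, which held 84.9% of the cells of LNP-P20-mAb 1 and 83.8% of those of LNP-P20-mAb 2. Each of the 36 clonotypes with 20 or more cells in these libraries combined was present in both. The remaining 14 pairs of libraries shared 0 or 1 such clonotype per pair. A TRBV19 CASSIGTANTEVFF clone with TRAV6-4, at 212 and 88 cells in LNP-P20-mAb 1 and 2, also had 1 cell in LNP-Ctrl 3, and a TRBV5 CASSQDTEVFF clonotype had 1 cell each in LNP-Ctrl 3 and LNP-P20-mAb 3.

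Of distinct TRB receptors compared by amino acids and thinned to 392 per library, LNP-P20-mAb 1 and 2 had 11.9% in common (Jaccard index), against 0.0511% to 0.376% in other pairs. Their Morisita-Horn index, which weights receptors by cells and reaches 1 for identical repertoires, was 0.968, and that of any other pair was at most 0.00356. Clone sizes in the pair were related (Spearman rho = 0.780 across the 36 clonotypes of 20 or more cells, which are not independent replicates) but differed by more than sampling noise, with a chi-square of 115 on 35 degrees of freedom over those clonotypes (p = 1.85e-10). The pair was kept as separate libraries because the labels list them so, which does not make them independent samples. Mean overlap within treatments exceeded that between treatments by 2.00 percentage points (exact permutation p = 0.1 over 10 splits), and with this pair left out the excess was 0.0379 points (exact permutation p = 0.2).

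**Figure D2:**
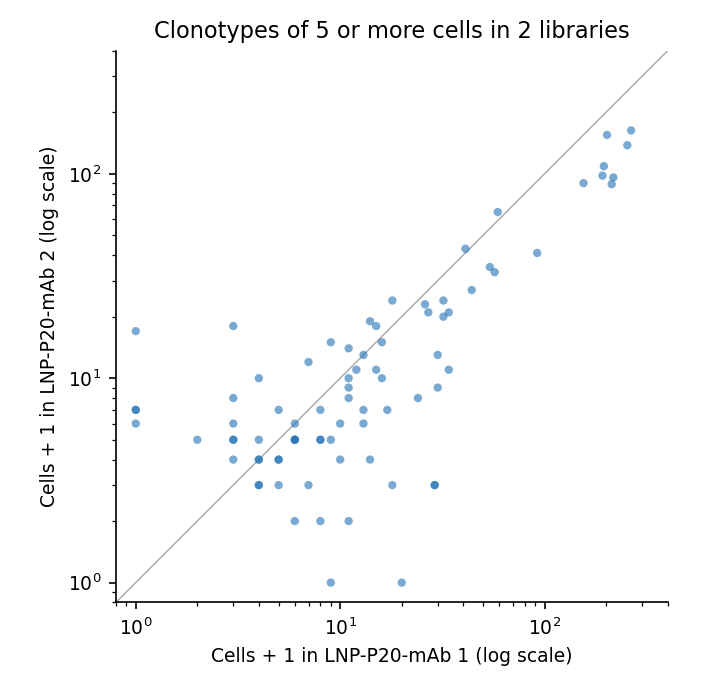
Cells per clonotype plus 1 in LNP-P20-mAb 1 (horizontal axis, log scale) and LNP-P20-mAb 2 (vertical axis, log scale), for clonotypes with 5 or more cells in both libraries combined; each point is 1 clonotype and the line marks equal numbers. Clonotypes of 20 or more cells all lie away from the axes, that is, were present in both libraries.

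By number of cells, the largest clone of the series was a TRBV20 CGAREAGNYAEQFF and TRAV7D-2 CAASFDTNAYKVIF clone of 468 cells in LNP-Ctrl 1, 14.04% of that library (95% exact Clopper-Pearson interval 12.9% to 15.3%, which covers counting error only, as do all such intervals here). LNP-P20-mAb 3 was led by a TRBV3 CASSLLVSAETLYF clone with TRAV7D-2 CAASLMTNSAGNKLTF at 414 cells, or 14.6% (13.3% to 15.9%), followed by a TRBV20 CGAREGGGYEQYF clone with TRAV7-3 at 114 cells. The top clone of both LNP-P20-mAb 1 and 2 joined TRBV15 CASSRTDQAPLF to TRAV9-2 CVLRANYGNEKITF, with 264 cells (8.09%, interval 7.18% to 9.08%) and 162 cells (8.04%, interval 6.89% to 9.31%). Next came TRBV13-1 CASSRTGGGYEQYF with TRAV12N-2 in LNP-P20-mAb 1 (253 cells) and TRBV3 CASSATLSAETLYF with TRAV7D-2 in LNP-P20-mAb 2 (154 cells). LNP-Ctrl 2 was led by TRBV12-1 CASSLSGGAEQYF with TRAV3-1 (92 cells, 2.35%) and TRBV26 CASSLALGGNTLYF with TRAV6N-6 (68 cells), and LNP-Ctrl 3 by TRBV3 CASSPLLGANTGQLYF with TRAV6D-6 (51 cells, 1.36%) and TRBV13-1 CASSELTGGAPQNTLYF with TRAV16N (20 cells). In LNP-Ctrl 1 the next clones, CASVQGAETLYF with TRAV7N-6 and TRBV12-2 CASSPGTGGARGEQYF with TRAV16, had 102 cells each.

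Few beta receptors recurred across libraries. Of the distinct TRB amino-acid receptors, 10022 were found in 1 library, 218 in 2, 17 in 3, 3 in 4 and 2 in 5. LNP-P20-mAb 1 and 2, with largely the same clones, alone had 118 receptors in common, including those also found elsewhere. TRBV19 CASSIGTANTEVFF was present in every library except LNP-Ctrl 2, with 305 cells in all, and TRBV10 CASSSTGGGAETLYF in every library except LNP-P20-mAb 3, with 15 cells. TRBV10 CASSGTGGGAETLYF (29 cells), TRBV3 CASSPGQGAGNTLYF (20 cells) and TRBV13-3 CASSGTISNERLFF (19 cells) were each present in 4 libraries. Receptors present in all 3 LNP-P20-mAb libraries and no LNP-Ctrl library numbered 4, namely TRBV16 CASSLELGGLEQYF (84 cells), TRBV15 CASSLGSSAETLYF (51 cells), TRBV5 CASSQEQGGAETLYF (26 cells) and TRBV16 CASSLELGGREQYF (22 cells). The reverse held for 3 receptors, TRBV31 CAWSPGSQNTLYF (9 cells), TRBV3 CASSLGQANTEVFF (8 cells) and TRBV16 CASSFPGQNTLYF (3 cells). This total of 7 compared with at most 4 in the other splits of the libraries (exact permutation p = 0.1, the smallest of 10 splits). These splits treat LNP-P20-mAb 1 and 2, which carried the same clones, as separate. With both pooled into 1 sample, an alternative chosen after the data were seen, the total was 11, the highest of the other splits of the 5 samples was 22, and the exact permutation p was 0.7.

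The clonotypes of LNP-P20-mAb tumours used fewer TRBV3, TRBV15 and TRBV31 segments and more TRBV12-2 and TRBV13-1 segments than those of LNP-Ctrl tumours, with every clonotype counted once. TRBV3 fell from 8.84% ± 1.13 of clonotypes in LNP-Ctrl to 2.87% ± 1.46 in LNP-P20-mAb libraries (SD, n = 3 each), a log2 change of -1.89 ± 0.24 (SE). TRBV12-2, whose product belongs to the Vβ5 family, rose from 4.35% ± 0.779 to 9.15% ± 0.714, a log2 change of 1.08 ± 0.16, and TRBV13-1, of the Vβ8 family, rose from 5.25% ± 1.83 to 9.39% ± 1.05, a log2 change of 0.76 ± 0.19. TRBV15 fell from 2.88% ± 0.484 to 0.945% ± 0.536 and TRBV31 from 4.85% ± 0.416 to 2.81% ± 0.654, with log2 changes of -1.36 ± 0.30 and -0.84 ± 0.20. Among alpha segments, TRAV12-1 rose from 1.18% ± 0.111 to 2.33% ± 0.657 and TRAV4N-4 fell from 1.66% ± 0.109 to 0.698% ± 0.537. LNP-P20-mAb 1 and 2, with largely the same clones, count as separate libraries here. With them pooled into 1 sample, TRBV13-1 and TRAV12-1 no longer passed the test of these segments.

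Of 152 V and J segments tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 3 were higher and 4 lower in LNP-P20-mAb libraries. The edgeR adjusted p was 3.43e-06 for TRBV3, 1.50e-05 for TRBV12-2, 0.00631 for TRBV15, 0.00973 for TRBV31, 0.0140 for TRBV13-1, 0.0366 for TRAV12-1 and 0.0470 for TRAV4N-4. Adjusted over each locus alone, edgeR called 7 of 22 TRBV, 0 of 75 TRAV, 0 of 43 TRAJ and 0 of 12 TRBJ segments. TRBV12-2 here means chains given that name alone, all with the CDR1 SGHLS, and chains that the deposited annotation names jointly for TRBV12-2 and TRBV13-2, 99.9% of which carry the CDR1 NNHNN found in every chain named TRBV13-2, were a segment of their own.

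Of the segment lists fixed before the data were examined, the Vβ8 family had 1 of 3 members higher (TRBV13-1), and 1 when adjusted over the list alone. TRBV13-2 and TRBV13-3 had log2 changes of -0.67 ± 0.41 and 0.19 ± 0.15. The Vβ5 family had 1 of 2 members higher, and 2 when adjusted over the list alone, TRBV12-1 being at 0.49 ± 0.18. The beta segments typical of iNKT cells (TRBV1 at -0.38 ± 0.20, TRBV13-2, TRBV29 at 0.25 ± 0.20) and of MAIT cells (TRBV13-2, TRBV13-3, TRBV19 at -0.12 ± 0.14) had 0 of 3 members called each, also when adjusted over the list alone. The V alpha segments nearest the J cluster, TRAV17 (-0.60 ± 0.49), TRAV19 (-0.08 ± 0.38) and TRAV21-DV12 (-0.91 ± 0.41), had 0 of 3 measured members called, also when adjusted over the list alone, and TRAV18 was too rare to test. With jointly named chains summed into TRBV13-2, an alternative chosen after the data were seen, its log2 change was -0.37 ± 0.14, not called over all segments (edgeR adjusted p = 0.128) but lower when adjusted over the Vβ8, iNKT or MAIT list alone (edgeR adjusted p = 0.0216, 0.0432 and 0.0432). DESeq2 called none of the members of the last 3 lists over all segments as named, and 30 of all 152 segments lay below an unadjusted p of 0.05 in edgeR.

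Large clones of TRBV3, those of 20 or more cells, held 6.16% to 15.9% of T cells in LNP-P20-mAb libraries, and large clones of TRBV15 held 8.09% and 8.04% in LNP-P20-mAb 1 and 2. Where large clones of a TRBV segment other than TRBV3 and TRBV15 held 5% or more of a library's cells, that segment was less frequent among the library's single-cell clonotypes than in other libraries in 6 of 10 cases (median log2 ratio -0.40), and in 5 of 7 with LNP-P20-mAb 1 and 2 averaged (median -0.58). For comparison, TRBV segments without large clones at that share were lower in 55 of 117 cases (median 0.020). TRAV segments with such clones were lower in 6 of 11 (median -0.14).

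Other segments with extreme estimates did not pass the test and are given as values. They were TRBV17 at a log2 difference of 0.67 ± 0.37, TRAV6-4 at 0.98 ± 0.44, TRAV13N-4 at 0.90 ± 0.43, TRAV7D-4 at -1.84 ± 0.61 and TRAV8D-1 at -1.09 ± 0.59. For J segments they were TRAJ50 at 0.76 ± 0.26, TRAJ7 at 0.68 ± 0.24, TRAJ24 at 0.63 ± 0.34, TRAJ2 at -1.52 ± 0.58, TRAJ6 at -1.12 ± 0.35, TRAJ43 at -0.81 ± 0.34, TRBJ2-1 at 0.32 ± 0.13 and TRBJ1-5 at -0.42 ± 0.23. The count of 7 calls was 16 without LNP-Ctrl 1, 2 without LNP-Ctrl 3, 4 without LNP-P20-mAb 1, 2 with DESeq2 and 4 with barcodes of 2 TRB chains kept. With cells counted instead of clonotypes edgeR called 0 segments (48 below an unadjusted p of 0.05), and the estimates of TRBV3, TRBV12-2, TRBV15 and TRAV12-1 changed sign, while TRBV13-1 (edgeR adjusted p = 0.132) and TRAV12-1 (0.0588) were no longer called with LNP-P20-mAb 1 and 2 pooled into 1 sample.

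**Figure D3:**
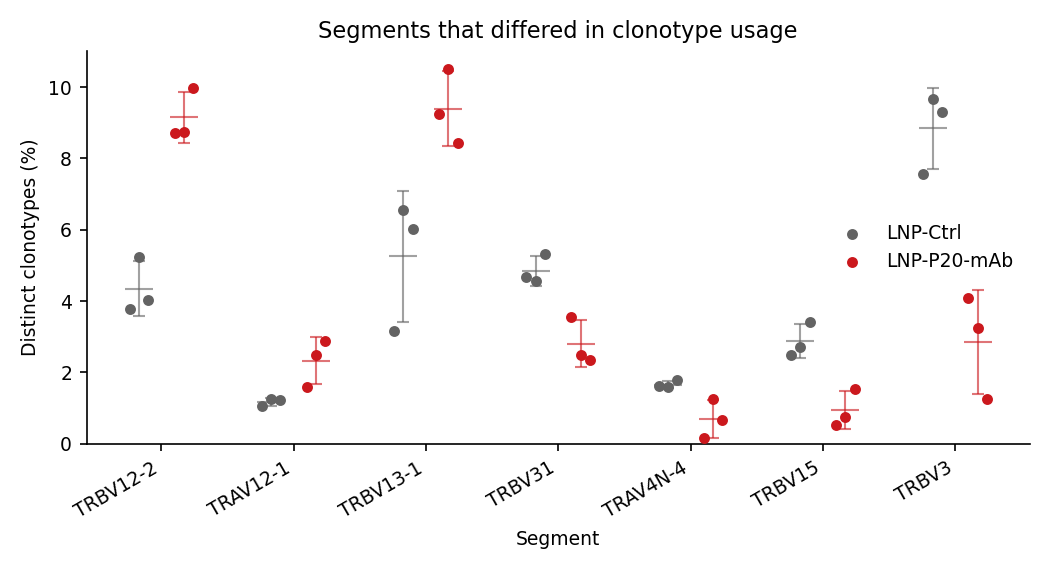
Share of distinct clonotypes (%, vertical axis) that use each of the 7 segments called between treatments; points are libraries, grey for LNP-Ctrl and red for LNP-P20-mAb, and horizontal marks with bars are the mean and SD of 3 libraries. TRBV3 lies between 7.56% and 9.67% in LNP-Ctrl and between 1.26% and 4.09% in LNP-P20-mAb libraries.

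Within libraries, the clonotypes that had expanded to 3 or more cells used TRAV7D-2, TRAJ7 and TRBV13-1 more often than single-cell clonotypes did. TRAV7D-2 was used by 7.31% ± 2.08 of expanded and 3.16% ± 0.834 of single-cell clonotypes (SD over n = 6 libraries), a log2 rise of 1.28 ± 0.30 that was present in 6 of 6 libraries (edgeR adjusted p = 0.00293). TRAJ7 was used by 5.72% ± 3.42 and 2.06% ± 0.348, a log2 rise of 1.34 ± 0.37 in 5 of 6 libraries (edgeR adjusted p = 0.0197), and TRBV13-1 by 11.5% ± 7.15 and 6.46% ± 1.79, a log2 rise of 0.75 ± 0.22 in 5 of 6 libraries (edgeR adjusted p = 0.0494). The shared clones of LNP-P20-mAb 1 and 2 enter this comparison in both libraries. With the pair pooled, TRAV7D-2 was still called (edgeR adjusted p = 0.0192), while TRAJ7 (0.229) and TRBV13-1 (0.316) were not. With the pair kept apart there were 3 higher and 0 lower among 152 segments in edgeR, compared over 468 expanded and 9784 single-cell clonotypes. No segment was called for a difference between the treatments in its relation to expansion (0 calls in edgeR, lowest adjusted p 0.947, 5 below an unadjusted p of 0.05). This test could miss differences, since even the comparison by expansion recovered 22.8% of simulated 2-fold changes.

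The Vβ8 list had 1 of 3 members higher (TRBV13-1), and 1 when adjusted over the list alone, and TRBV13-2 and TRBV13-3 stood at -1.33 ± 0.96 and 0.18 ± 0.25. TRBV13-2 by that name alone is rare, and with jointly named chains summed into it (36 expanded and 1110 single-cell clonotypes) it stood at -0.50 ± 0.23, not called over all segments (edgeR adjusted p = 0.241) but lower when adjusted over the Vβ8 list alone (0.0479), and not over the iNKT (0.0519) or MAIT (0.0958) list. The Vβ5 list had 0 of 2 members called over all segments and 2 lower when adjusted over the list alone, TRBV12-1 at -0.69 ± 0.29 and TRBV12-2 at -0.87 ± 0.30. The iNKT beta list (TRBV1 0.65 ± 0.30, TRBV29 -0.66 ± 0.34), the MAIT beta list (TRBV19 0.22 ± 0.24) and the V alpha list (TRAV17 -0.26 ± 1.07, TRAV19 -0.28 ± 0.71, TRAV21-DV12 -0.97 ± 1.01) each had 0 of 3 members called, also when adjusted over the list alone (22 of all 152 segments lay below an unadjusted p of 0.05 in edgeR). Other extreme values that did not pass were TRAJ5 at 1.71 ± 0.59, TRAV10N at 1.36 ± 0.62, TRAJ4 at 1.23 ± 0.49, TRAV6-4 at 1.17 ± 0.68, TRBV15 at 0.76 ± 0.44 and TRBJ2-4 at 0.39 ± 0.21 on the higher side. On the lower side were TRAJ47 at -1.72 ± 0.92, TRAJ35 at -1.60 ± 1.25, TRBV30 at -1.29 ± 1.27, TRBV14 at -1.01 ± 0.43 and TRBJ1-6 at -0.81 ± 0.48. TRAV11, TRAV13N-1, TRAV13-4-DV7 and TRAJ2, used by 64, 76, 77 and 66 single-cell clonotypes, had 0 among the 468 expanded ones, which allows a share of up to 0.641%.

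DESeq2 called 0 of 67 segments with an adjusted p (22 below an unadjusted p of 0.05). edgeR called 0 without LNP-P20-mAb 3, 1 without LNP-P20-mAb 1 or without LNP-P20-mAb 2, and 1, TRAV7D-2, with those 2 pooled. TMM scaling, which shifted the median log2 value by -0.30, left 0 higher and called 3 lower, where the unscaled split was 3 higher and 0 lower.

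Cells of expanded clonotypes also carried more receptor UMIs. The median number of TRB UMIs per cell was 1.33-fold that of single-cell clonotypes (log2 ratio 0.41 ± 0.19 SD, higher in 6 of 6 libraries, exact sign-flip permutation p = 0.03125, the smallest of 64 flips). For TRA UMIs it was 1.31-fold (log2 ratio 0.39 ± 0.19 SD, 6 of 6 libraries, exact sign-flip permutation p = 0.03125). With LNP-P20-mAb 1 and 2 as 1 sample both exact p-values were 0.0625, the smallest that 5 samples allow. TRB CDR3 loops of expanded clonotypes differed from those of single-cell clonotypes by -0.00722 ± 0.102 amino acids (exact sign-flip permutation p = 0.9375, n = 6), and TRA CDR3 loops by 0.141 ± 0.153 (exact sign-flip permutation p = 0.09375, n = 6), or by 0.00109 with expansion taken as 2 or more cells (exact sign-flip permutation p = 0.9375). For 3 or more cells that TRA difference was 0.267 in LNP-Ctrl and 0.0147 in LNP-P20-mAb libraries (n = 3 each; exact permutation p = 0.1), and for 2 or more cells 0.0293 and -0.0271 (exact permutation p = 0.3). Between treatments, the mean TRB CDR3 length was 14.02 amino acids in LNP-P20-mAb and 13.97 in LNP-Ctrl libraries (exact permutation p = 0.2), and the mean TRA CDR3 length was 13.71 and 13.66 (exact permutation p = 0.3).

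Invariant T cell receptors were rare and sat in unexpanded clonotypes. The alpha chain of iNKT cells (TRAV11 or TRAV11D joined to TRAJ18), which recognise lipids on CD1d, was carried by 0.414% ± 0.129 of LNP-Ctrl and 0.124% ± 0.0779 of LNP-P20-mAb T cells (SD, n = 3 each), groups that did not overlap (exact permutation p = 0.1). These were 12, 22 and 12 cells in the LNP-Ctrl and 2, 2 and 6 in the LNP-P20-mAb libraries, with 95% exact Clopper-Pearson intervals from 0.166% to 0.848% in LNP-Ctrl and from 0.00742% to 0.459% in LNP-P20-mAb libraries. All 56 were single-cell clonotypes, 50 had the TRA CDR3 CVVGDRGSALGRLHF, and 42 (75.0%) had a TRBV1, TRBV13-2 or TRBV29 beta chain, jointly named chains included. As a share of clonotypes they made up 0.576% ± 0.196 and 0.433% ± 0.0726 (n = 3 each; exact permutation p = 0.4). The TRAV1 and TRAJ33 alpha chain of MAIT cells, which recognise microbial vitamin B metabolites on MR1, was found in 17 cells in all, 0.124% ± 0.0734 of LNP-Ctrl and 0.0352% ± 0.0609 of LNP-P20-mAb T cells (n = 3 each; exact permutation p = 0.2). That difference of -0.0885 percentage points was -0.0483 without LNP-Ctrl 2. LNP-P20-mAb 1 and 2 had 0 such cells among 3263 and 2016, which allows shares of up to 0.0919% and 0.149%.

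Barcodes with 2 TRB chains, or with 3 TRA chains, are candidate doublets and were 10.5% ± 2.13 of LNP-P20-mAb and 5.68% ± 0.496 of LNP-Ctrl barcodes, without overlap (SD, n = 3 each; exact permutation p = 0.1). Counting only pairs of different TRBV segments turned this around, at -2.25 percentage points for LNP-P20-mAb against LNP-Ctrl (exact permutation p = 0.2). Paired cells with 2 TRA chains made up 13.2% ± 9.22 and 12.6% ± 1.60 (n = 3 each; exact permutation p = 1), and LNP-P20-mAb 3 stood apart at 23.8%. With every clonotype counted once the difference was -1.65 points (exact permutation p = 0.1). Of 392 distinct TRB receptors per library, 2.69% ± 0.920 in LNP-P20-mAb and 1.44% ± 0.0613 in LNP-Ctrl had a neighbour of the same TRBV and length at 1 amino-acid difference (n = 3 each; exact permutation p = 0.1), but without thinning the difference was -4.10 points (exact permutation p = 0.1). TRAJ segments numbered 40 or more, near the V segments, were used by 28.5% ± 1.80 and 27.0% ± 0.256 of clonotypes (n = 3 each; exact permutation p = 0.4). TRAJ segments numbered 20 or less were used by 23.8% ± 2.04 and 24.4% ± 0.992 (n = 3 each; exact permutation p = 0.8). Weighted by cells, those differences became -5.87 points for the near segments (exact permutation p = 0.2) and 12.2 points for the far ones (exact permutation p = 0.1).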

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

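All tests of explanations in this part, with their limits, were chosen after the results were seen.

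Barcodes with 2 TRB chains were set aside before the comparisons, and their make-up differed between libraries. Barcodes whose 2 TRB chains use the same TRBV segment made up 8.67% ± 3.24 of LNP-P20-mAb barcodes and 1.60% ± 1.44 of LNP-Ctrl barcodes (SD, n = 3 each; exact permutation p = 0.1). They were 95.9%, 88.6% and 60.4% of the 2-TRB barcodes of LNP-P20-mAb 1, 2 and 3 and 56.5%, 20.5% and 6.55% of those of LNP-Ctrl 1, 2 and 3, where random pairs of cells would give 5.80% to 9.02%. Among barcodes with 2 TRA chains, pairs of the same TRAV were at most 2.21%. In each treatment the libraries ranked by same-TRBV share as they did by expanded share, so treatment and expansion cannot be told apart here. The UMI ratio of the lesser to the greater TRB chain was 0.158 to 0.556 for the same TRBV and 0.5 to 0.667 for different TRBV segments.

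The length of the TRB CDR3 loop in expanded against single-cell clonotypes went opposite ways in the treatments. It was shorter in every LNP-Ctrl library (mean difference -0.0823 amino acids) and longer in every LNP-P20-mAb library (mean difference 0.0679), a gap of 0.150 amino acids (n = 3 each; exact permutation p = 0.1, the smallest possible). The difference was -0.0182, -0.171 and -0.0574 in LNP-Ctrl 1, 2 and 3. In LNP-P20-mAb 1, 2 and 3 it was 0.109, 0.0843 and 0.0107. The higher treated values, of LNP-P20-mAb 1 and 2, came from libraries with largely the same clones. This result was picked because the treatments split by sign, which alone gives that p. With expansion taken as 2 or more cells the loop was longer in LNP-Ctrl 1 (0.0304), so the split by treatment did not hold in every library. For TRA the gap at 3 or more cells was in the other direction (-0.252 amino acids, from 0.267 in LNP-Ctrl to 0.0147 in LNP-P20-mAb, exact permutation p = 0.1), but at 2 or more cells it was -0.0563 with overlapping treatments (exact permutation p = 0.3), where that of TRB was 0.136 (exact permutation p = 0.1).

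LNP-P20-mAb 1 and 2 shared 100% of their 36 clonotypes of 20 or more cells. Transcripts that crossed between the libraries after barcoding are argued against by the barcodes. Of these, 15 were found in both libraries where other pairs predict 14.2, and 1 of the 7 usable ones carried the same clonotype. Cells that crossed before barcoding would have received other barcodes, so this test cannot address them. Receptors that arise often in separate animals are argued against by the other pairs, of which none shared more than 1 paired clonotype, and a single library deposited in both places by clone sizes that differed beyond sampling noise (chi-square p = 1.85e-10). T cells drawn from 1 animal, or from pooled tumours, would share large clones to this extent and remain a candidate explanation, with no label that settles it. That sharing raised the question, so it is no separate test. The differing clone sizes bear equally on 1 cell suspension split between both libraries. If T cells came from 1 animal or from pooled tumours, LNP-P20-mAb is represented by 2 rather than 3 independent samples.

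The expanded share of LNP-P20-mAb libraries exceeded that of LNP-Ctrl libraries by 48.7 percentage points after thinning to equal cell numbers, more than the control SD of 19.96, so cell number per library does not account for it. Without thinning the gap was 46.95 points, and adding back, also without thinning, the single cells that seem to be missing beside large clones of the same TRBV left 46.5. A smaller number of unexpanded T cells beside otherwise similar expanded ones stays open, since within cells of clonotypes of 3 or more the share of the 10 largest differed by 3.65 points, under the control SD of 4.55. Without thinning, clonotypes of 3 or more cells numbered 83.3 ± 18.8 per LNP-P20-mAb and 72.7 ± 26.6 per LNP-Ctrl library. Those of 20 or more cells numbered 18.3 ± 7.02 and 7.67 ± 5.13 (n = 3 each, exact permutation p = 0.2, or 0.3 with LNP-P20-mAb 1 and 2 as 1 sample). This count cannot decide the question, since with fewer unexpanded cells in a library alike clones would be sampled at more cells each. With 3 libraries a difference could be missed. Whether LNP-P20-mAb enlarged clones, kept unexpanded T cells out or did neither was not tested further, as the gene expression samples that would identify those cells were not analysed here. The libraries of each treatment also differ widely among themselves, from 9.45% to 48.6% in LNP-Ctrl.

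TRBV3 and TRBV15 fell among LNP-P20-mAb clonotypes while their estimates by cells were log2 0.26 and 1.16, neither called, and large clones of both segments were present there. With the 2-TRB barcodes kept, each by its TRB chain of most UMIs alone, TRBV3 was still lower by log2 -1.54 (edgeR adjusted p = 0.0179, against 5.99e-22 to 0.633 over its alternatives) and TRBV15 by log2 -1.27 (edgeR adjusted p = 0.0281). Leaving out those leading chains is thus argued against as the whole cause. The second TRB chain of such barcodes stayed out in either case, so this alternative cannot decide whether its absence matters. A loss of single cells whose TRBV matches a large clone, somewhere between droplet and deposited file, stays open and was not decided by the segments outside this pattern: other TRBV segments of large clones had a median log2 ratio of -0.40 among single-cell clonotypes, or -0.58 with LNP-P20-mAb 1 and 2 averaged, and ran from -3.34 for TRBV20 in LNP-Ctrl 1 to 0.28 for TRBV13-1 in LNP-P20-mAb 2. The median was 0.020 for TRBV segments without large clones and -0.14 for TRAV segments with them. TRBV31 is not covered by a loss beside large clones, because its large clones held at most 1.13% of cells in any LNP-P20-mAb library, and an effect of the treatment stays open for TRBV3, TRBV15 and TRBV31, as untested.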

How the results depend on the processing

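Alternatives with LNP-P20-mAb 1 and 2 as 1 sample or their pair left out, with jointly named segments summed, with missing cells added back, with 2-TRB barcodes kept, with different-TRBV pairs alone, or with clonotypes counted once or without the largest for dual alpha chains were chosen after the data were seen, while the others were set before. Of 319 alternative values of the main results, 275 kept their direction and their side of the threshold, 14 kept the direction without passing, 16 reversed and 14 moved, and of 145 for the called segments 88 did, 53 kept the direction without passing and 4 reversed. Most tests between treatments cannot pass 0.05 in this design, so an unchanged side says little about their stability. The gap in expanded share ranged from 40.0 to 59.6 percentage points over its 15 alternatives. Depth limits rare classes, where the smallest library allows up to 0.149% for a count of 0.

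The cause of the following shifts was not tested, except where the construction gives it. Values are LNP-P20-mAb minus LNP-Ctrl. Candidate doublets came to -2.25 points with different-TRBV pairs alone. Dual alpha cells came to -1.65 points with clonotypes counted once and -2.84 without the largest clonotype, and ranged from -4.75 (without LNP-P20-mAb 3) to 3.33 points with single libraries left out. Clonotypes of 2 to 4 cells came to 0.669 points with LNP-P20-mAb 1 and 2 as 1 sample and ranged from -2.34 to 1.11 points with single libraries left out. Similar CDR3 loops came to -4.10 points without thinning, where larger libraries hold more receptors. Weighted by cells, TRAJ usage came to -5.87 points (near) and 12.2 points (far), and the far share ranged from -1.19 to 0.605 points with single libraries left out. The paired share ranged from -0.180 (without LNP-Ctrl 2) to 2.58 points. With single libraries left out, other wide ranges were 0.770 to 2.51 points for near TRAJ usage, -1398 to -534 recovered T cells, 1.33 to 4.83 TRB and 0.833 to 2.33 TRA UMIs per cell, 0.0269 to 0.0612 amino acids for TRB CDR3 length, 3.45 to 6.92 points for clonotypes of 10 to 19 cells, -0.124 to -0.0483 points for MAIT-type cells and 0.00643 (without LNP-P20-mAb 2) to 3.04 points for receptor overlap. The expanded minus single TRB length ranged from -0.0304 to 0.0256 amino acids with single libraries left out. UMI log2 ratios ranged from 0.35 to 0.46 (TRB) and from 0.33 to 0.44 (TRA) with single libraries left out and came to 0.41 and 0.43 with LNP-P20-mAb 1 and 2 as 1 sample, all at an exact p = 0.0625, the smallest that 5 libraries allow. Public receptors (7) came to 12 by CDR3 amino acids alone and 11 with LNP-P20-mAb 1 and 2 as 1 sample.

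Segment calls between treatments (7 in edgeR) numbered 2 with DESeq2 (15 below an unadjusted p of 0.05), 4 with 2-TRB barcodes kept, and 0 with cells counted, where the log2 estimates were -0.19 for TRAV12-1, -0.48 for TRBV12-2, 1.16 for TRBV15 and 0.26 for TRBV3. They ranged from 2 (without LNP-Ctrl 3) to 16 (without LNP-Ctrl 1). TRBV3 and TRBV12-2 kept their calls under 14 of 15 alternatives, TRBV15 and TRBV31 under 11 of 15, TRBV13-1 under 9 of 15, and TRAV12-1 and TRAV4N-4 under 5 of 15 and 5 of 14. By expansion, TRAV7D-2 kept its call under 10 of 13, TRAJ7 under 5 of 14 and TRBV13-1 under 4 of 14. Calls by expansion (3 in edgeR) numbered 0 of 67 with DESeq2 (22 below an unadjusted p of 0.05), 1 with D and N copies summed and 1 with LNP-P20-mAb 1 and 2 as 1 sample, and ranged from 0 (without LNP-P20-mAb 3) to 4 (without LNP-Ctrl 1). TMM scaling gave 0 higher and 3 lower instead of 3 higher and 0 lower. TRAV4N-4 and TRAV7D-2 have no value of their own with copies summed, where the 1 call by expansion was TRAV7-2 (log2 1.28, edgeR adjusted p = 0.00904). Libraries with the same number did not deviate together (r = -0.0431, -0.0867 and -0.0546 for numbers 1, 2 and 3, and no library correlates best with its own number). With the replicate number as a block, edgeR called 5 segments between treatments, the gap in expanded share stayed 48.7 points (exact permutation p = 0.25, the smallest of that test), and the other single-value differences kept their values by construction.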

Other observations

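The tests of alike TRA CDR3 loops, of iNKT-type cells among single-cell clonotypes and of other splits of the libraries were chosen after the results were seen.

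Expanded clones of different samples paired near-identical TRA CDR3 loops with the same TRBV segment, whatever their TRAV segment. Among 422 clonotypes of 3 or more cells, with LNP-P20-mAb 1 and 2 pooled, 136 pairs from different samples had TRA CDR3 loops of equal length with at most 1 amino-acid difference, and 74 of these pairs also shared the TRBV segment. Shuffled beta chains gave 7.96 such pairs on average and at most 18 in 1000 permutations, a 9.30-fold excess (permutation p = 0.001, the smallest they can give). Single-cell clonotypes gave 1935 pairs where 1492 were drawn by shuffling, a 1.30-fold excess. The excess of expanded clonotypes lay between 8.07-fold and 10.9-fold with each sample left out in turn.

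Several families stand out. TRBV1 with the TRA CDR3 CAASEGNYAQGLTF (TRAJ26) made up 5 clonotypes and 259 cells in 4 samples, 54 cells in LNP-Ctrl 2, 3 in LNP-Ctrl 3, 126 in LNP-P20-mAb 1 and 2 together and 76 in LNP-P20-mAb 3. Their TRAV segments differed, with TRAV5-4 in the LNP-Ctrl libraries and TRAV14-1 or TRAV14N-1 in the LNP-P20-mAb libraries. TRBV15 with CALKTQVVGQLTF (TRAJ5) made up 5 clonotypes and 102 cells in 4 samples, 26, 24 and 3 of them in LNP-Ctrl 1, 2 and 3 and 49 in LNP-P20-mAb 3. TRBV10 with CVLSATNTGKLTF (TRAJ27) made up 4 clonotypes and 30 cells in 3 samples. The TRBV19 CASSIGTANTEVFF and TRAV6-4 clone of LNP-P20-mAb 1 and 2 had a counterpart in LNP-Ctrl 2, TRBV19 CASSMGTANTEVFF with TRAV6-4, at 57 cells. These families were named after their values were seen.

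A candidate explanation, as a hypothesis, is that expanded T cells of separate samples recognise shared targets of this tumour line. It would give an excess above that of single-cell clonotypes, and the values were 9.30-fold and 1.30-fold. The rule compared only the TRA CDR3 and the TRBV name. Of the 74 pairs, 62 had TRB CDR3 loops of equal length and 23 had at most 1 amino-acid difference there. Pairs of the same family are not independent. Cells carried over between libraries would leave identical bases, and of the 74 pairs 0 were identical in the bases of both chains, 1 in TRB and 21 in TRA. Pairs between the treatments numbered 41 and pairs within a treatment 33, so such families were found in both. What the receptors bind was not measured, and the similarity rule was set after examples had been seen.

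The lower iNKT-type share in LNP-P20-mAb libraries may follow from there being fewer unexpanded T cells. All iNKT-type cells were single-cell clonotypes, and as a share of single-cell clonotypes the treatments overlapped, with a ratio of LNP-P20-mAb to LNP-Ctrl of 0.865 (means over n = 3 libraries each), although only 10 iNKT-type cells were seen in LNP-P20-mAb libraries.

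Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called as many as 7 segments between treatments, and the highest other split called 0, but 10 splits are too few for a share under 0.05. For usage by expansion, 1 of 32 sign flips, the real one, called as many as 3 segments and the highest other flip called 1. A share of 1 in 32 is the smallest these flips can give. The test was chosen after the calls were seen, so it cannot exclude chance, and it treats LNP-P20-mAb 1 and 2 as independent. With these as 1 sample the real arrangement called 1 segment and the highest other flip also 1 (2 of 16 flips called as many, the real one included), and 16 flips are too few for a share under 0.05. The difference of that effect between treatments had 0 calls, and the highest other split called 1. Any split reaches 0 calls whatever the data hold, so this comparison decides nothing.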
